A study of Mus musculus with 19 samples.

How the data were processed

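The deposited values of 19 mouse arrays (Affymetrix Clariom D, also called MTA 1.0) were analysed without the publication. Per the labels, each array held the RNA of the infrarenal aorta of 1 C57BL/6J mouse aged 10 weeks, taken 7 days after infusion for 5 min at 120 mmHg of elastase at 2.5 U/mL or of saline. RNA was extracted with TRIzol, and 100 ng per mouse were labelled with the WT PLUS kit. The values are log2 intensities as deposited, which the authors made with the Transcriptome Analysis Console on the mm10 annotation, per the labels. The version of that software, the summarisation and the background correction are not given in the sources used here. The values have 2 decimals and differ in median between male and female arrays. They were used without further normalization in the main tests.

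The value table held 65956 probe sets. Of these 30604 carried 1 gene symbol in the gene annotation of the platform, 2146 carried several and 33206 were not listed there. Symbols were updated for 827 probe sets against the mouse RefSeq annotation of GRCm38.p6, which also gave the coordinates. For the 355 genes with more than 1 probe set the brightest was kept, which left 30142 genes, of which 22398 had a RefSeq entry. Probe sets with several symbols or none were tested only in the closing section. No gene was left out for low signal in the main tests. At most 2.50% of values were identical between any pair of arrays, so no array was a copy of another.

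Arrays were grouped by the sex and treatment in their titles: 3 female sham, 4 female PPE, 5 male sham and 7 male PPE. Group means were fitted over all 19 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, version 1.17.8 of data.table for reading), with 1 residual variance per gene shared by the groups. The contrasts were PPE against sham in each sex and averaged over the sexes, male against female at each condition, and the difference of the PPE response between the sexes (male minus female). Genes were called at a Benjamini-Hochberg adjusted p below 0.05 over the 30142 genes. No block was used, since the labels do not say that the replicate numbers in the titles mark a shared litter, batch or day, and each array held another mouse.

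The analysis plan held 39 gene lists written before the data were examined. Each list was tested with camera at a preset correlation between genes of 0.01, two-sided, with adjustment over the 39 lists, and again with an estimated correlation and with fry. The members called higher, lower or not called were counted over all genes and adjusted over the list alone. Genes were named by rule. In each sex these were the 12 largest rises and falls among called genes with complete separation of PPE and sham arrays, and in comparisons with sex up to 10 genes per direction. Each list also gave its first 2 members and the 2 with the lowest p in the averaged contrast, and Xist, Ddx3y, Kdm5d and Eif2s3y were named for sex, of which Ddx3y is not reported here. Predicted genes, small RNA genes and antigen receptor segments were skipped. Symbol families and the clock score were chosen after the values were seen.

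Correlations between scores used deviations from the group means with permutation tests. Values of r without the 2 farthest arrays kept deviations from group means that included those arrays. Clock scores, chosen after the values were seen, were described by means, errors and the 95% interval of the difference between the sexes. Groups were split in up to 100 other ways with seed 1. Alternatives were quantile normalization, median centring, a filter on dim genes, every probe set, the mean of a gene's probe sets, an intensity trend with robust prior, array weights, only the groups compared, a replicate block, a 2-fold screen, each array left out in turn, male groups drawn down 100 times to the female sizes, and lists of the sex chromosomes left out. Chosen after the results were seen were 3 male arrays left out or marked by a term, clock and adipocyte scores as covariates, and sensory receptor and small RNA genes left out. The procedure was tested on simulated data with changes of 0.5, 1 and 2 log2 units. It recovered 49.2%, 92.5% and 100% of changed genes in males, 43.3%, 80.6% and 98.5% in females, and 22.4%, 67.2% and 93.9% for the sex difference, with 3, 7 and 9 unchanged genes called. All 5 shifted lists and 0 of 34 others were called. The simulated genes varied independently of each other, so this does not show how often lists are called wrongly when their members vary together.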

Results

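Gene expression was measured in the infrarenal aorta of male and female C57BL/6J mice, an inbred laboratory strain, 7 days after infusion of saline (sham) or of porcine pancreatic elastase (PPE). Elastase digests elastin, and its infusion under pressure is a standard way to induce an abdominal aortic aneurysm in mice. The 19 arrays, 1 mouse per array, comprised 3 female sham, 4 female PPE, 5 male sham and 7 male PPE aortae, and these numbers limit the precision of every value below. After reduction to 1 probe set per gene, 30142 genes were compared on the log2 scale of the deposited values. The design implies the response to PPE in each sex, the difference between these responses, and the difference between the sexes at each condition. Median values per array over all 65956 probe sets lay between 6.17 and 6.31 in the 7 female arrays (6.24 ± 0.05, SD) and between 5.61 and 5.85 in the 12 male arrays (5.71 ± 0.07). Xist, the non-coding RNA of the inactive X chromosome (X: 103460373 to 103483233, mm10), averaged 16.33 and 16.46 in female sham and PPE aortae and 5.38 and 5.41 in the male groups. The Y-linked Kdm5d and Eif2s3y were higher in every male than in every female array, as labelled.

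In males, PPE was followed by a rise of chemokine, T and NK cell and MHC class II genes and by a fall of smooth muscle and pericyte genes. Interferon-stimulated, macrophage and neutrophil lists also rose with the preset correlation, with adjusted p = 0.117, adjusted p = 0.0756 and adjusted p = 0.0527 with an estimated correlation. The largest rise among the genes named by rule was that of Slfn4, a Schlafen family gene of myeloid cells (11: 83175172 to 83190216), from 8.74 in sham to 13.93 in PPE (log2 difference 5.19 ± 0.60, SE, 36.4-fold, adjusted p = 7.75e-06, n = 5 and 7). Cxcl9, a chemokine induced by interferon gamma (5: 92321331 to 92328079), rose by 4.68 ± 0.46 (25.6-fold, adjusted p = 1.67e-06), and the acute-phase gene Saa3 rose by 4.00 ± 0.40 (16.0-fold, adjusted p = 2.09e-06). The largest fall among the genes named by rule was that of Itga8, the integrin alpha 8 chain of contractile cells (2: 12106632 to 12301985), from 15.74 to 12.30 (−3.44 ± 0.35, 10.8-fold, adjusted p = 2.54e-06). Myh11, the smooth muscle myosin heavy chain (16: 14194527 to 14292188), fell by 2.90 ± 0.36 on the log2 scale (7.46-fold, adjusted p = 1.44e-05).

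The other rising genes named by rule in males were Ms4a4c (4.39), Slfn1 (4.03) and Acod1, which makes itaconate in activated macrophages (3.71). They also included the Fc receptor genes Fcgr4 (3.68) and Fcgr1 (3.31), Il1b, which encodes interleukin 1 beta (3.65), Klra2 of the Ly49 receptor family (3.64) and AW112010 (3.43). Ccl5 rose by 3.40, with male sham 4 at 7.03 against 7.55 to 7.76 in the other sham arrays. The falling genes were Ccdc3 (−3.27), the muscle LIM gene Pdlim3 (−2.76), Cytl1 (−2.69), and the integrin ligand gene Npnt (−2.69). To these came the small heat shock gene Hspb7 (−2.67), Dmd, which encodes dystrophin (−2.64), Fmo2 (−2.62), the sarcomere gene Myom1 (−2.59), Synpo2 (−2.56) and Susd5 (−2.55). The rule admitted only genes for which all 7 PPE arrays lay on the same side of all 5 sham arrays. Each of the 24 kept its call in all 19 fits that left out 1 array. A further 1 rising and 4 falling transcripts of that size had names of predicted genes, small RNA genes or receptor segments and are not named. In all, 5923 genes were called in males, 2916 higher and 3007 lower after PPE (49.2% higher), of which 1217 changed at least 2-fold. With each array centred on its median, 60.3% of the 5621 called genes were higher. Splits of the male arrays into other groups of the same sizes called at most 1866 genes, below the real count. They called up to 27 lists against 16, so chance cannot be excluded for the count of lists with the preset correlation.

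Immune cell and inflammatory lists rose in males. All 15 measured T and NK cell markers rose (median log2 change 1.48, adjusted p = 1.01e-17, and 0.0161 with an estimated correlation). Cd3e of the T cell receptor complex rose by 2.08, Cd8a by 1.30, the cytotoxic granule gene Gzma by 2.10 and Klrd1 by 2.42. Of the MHC class II and dendritic cell genes 11 of 13 rose and 2 were not called (median 1.24, adjusted p = 3.2e-14, and 0.0134 with an estimated correlation), with H2-Aa at 2.08 and the class II transactivator gene Ciita at 1.75. Among chemokines 16 of 19 rose and 3 were not called (median 1.70, adjusted p = 1.3e-13, and 0.0134 with an estimated correlation), including Ccl2 (1.66) and Cxcl12 (0.75). Of the inflammatory cytokine and inflammasome genes 12 of 18 rose and 6 were not called (median 1.12, adjusted p = 3.22e-12, and 0.0393 with an estimated correlation). Their members included the interleukin 1 receptor antagonist gene Il1rn (2.76) and Tnfaip3, a brake on NF-kappa B signalling (1.32), while Il6 stood at 1.29 without passing (adjusted p = 0.15). All 14 interferon-stimulated genes rose (median 2.50, adjusted p = 3.14e-13), among them Ifit1 (2.36), Gbp2 (2.75) and Bst2 (2.67), and the list had adjusted p = 0.117 with an estimated correlation. Monocyte and macrophage markers rose in 15 of 18 members (median 1.44, adjusted p = 1.94e-13, and adjusted p = 0.0756 with an estimated correlation). Cd68 rose by 1.66 and Adgre1, which encodes F4/80, by 2.12. Neutrophil markers rose in 9 of 12 members (median 1.61, adjusted p = 8.86e-09, and adjusted p = 0.0527 with an estimated correlation). The calprotectin genes S100a8 (2.93) and S100a9 (2.87) and the receptor gene Csf3r (2.49) were among them.

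The contractile and mural cell lists fell in males. Of 17 smooth muscle contractile genes 14 fell and 3 were not called (median −1.89, adjusted p = 1.38e-15, and 0.0497 with an estimated correlation). Acta2, the smooth muscle actin gene, fell by 0.74 from 18.58, a value above the 99th percentile of every array (16.58 to 17.33). Smtn fell by 1.78 and Cnn1 by 2.49. Pericyte markers fell in 6 of 8 members (median −0.96, adjusted p = 4.5e-06, and 0.0134 with an estimated correlation), among them Rgs5 (−1.81), the potassium channel subunit gene Abcc9 (−1.36) and Mcam (−1.08). Endothelial markers fell in 6 of 13 members (median −0.48, adjusted p = 0.000655, and adjusted p = 0.183 with an estimated correlation). The angiopoietin receptor gene Tek was at −0.89 and Pecam1 at −0.48, while Cdh5 was at −0.07 without a call. Resident fibroblast markers fell in 7 of 9 members (median −0.74, adjusted p = 0.00031, and adjusted p = 0.2 with an estimated correlation). Cd34 was at −0.82 and Pi16 at −0.74. Dcn was not called, at 18.39 to 18.77 in the male arrays, above the 99th percentile of every array, where a change may be hidden. Circadian clock genes fell in 9 of 14 members (median −0.62, adjusted p = 0.00017, and adjusted p = 0.0695 with an estimated correlation). The output gene Dbp was at −1.23, and the male sham arrays spanned a wide range of Dbp, Arntl and Npas2 values.

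Glycolysis, cell cycle, lysosome and complement lists rose in males, of which only the first kept the call with an estimated correlation. Glycolysis and hypoxia genes rose in 11 of 17 members and fell in 1 (median 0.36, adjusted p = 1.62e-05, and 0.0393 with an estimated correlation). Among them were the glucose transporter gene Slc2a1 at 1.05, hexokinase 3 (Hk3) at 1.04, Ldha at 0.52 and the falling member Ndrg1 at −0.57. Cell cycle genes rose in 15 of 22 members (median 0.50, adjusted p = 3.63e-09, and adjusted p = 0.291 with an estimated correlation). Top2a was at 0.81 and Mcm5 at 0.65, and Mki67 was at 0.63 without a call. Lysosome genes rose in 8 of 14 members (median 0.44, adjusted p = 1.89e-06, and adjusted p = 0.183 with an estimated correlation), with the cholesterol carrier gene Npc2 at 0.99 and Ctsz at 0.81. Complement and coagulation genes rose in 5 of 12 members and fell in 1 (median 0.72, adjusted p = 0.000923, and adjusted p = 0.183 with an estimated correlation), with factor B (Cfb) higher by 4.92-fold and the integrin gene Itgb2 at 1.79.

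The matrix lists did not pass as groups in males, although members did. Elastic fibre genes (adjusted p = 0.0725) fell in 5 and rose in 1 of 12 members, with elastin (Eln) at −1.16 ± 0.21 and Ltbp4 at −1.56. Fibrillar collagens and their processing enzymes (adjusted p = 0.266) fell in 1 of 16, the prolyl hydroxylase gene P4ha2 (−0.30), while Col1a1 and Col3a1 were not called, at values of 18.81 to 19.41 in the male arrays that lie above the 99th percentile of every array and may hide a change. Matrix proteases (adjusted p = 0.0905) rose in 5 of 18, with the gelatinase gene Mmp9 at 1.86, the neutrophil collagenase gene Mmp8 at 1.30 and Adam8 at 1.43, whereas Mmp2 was at −0.35 without a call. Among protease inhibitors (adjusted p = 0.324) Timp1 rose by 0.93 and 4 of 9 members fell, including Timp4 (−1.27) and Reck (−1.18). TGF-beta and BMP pathway genes (adjusted p = 0.0607) rose in 1 and fell in 7 of 19, with Tgfb1 at 0.67, Tgfb3 at −0.92 and Ltbp1 at −2.11. Activated fibroblast genes (adjusted p = 0.514) rose in 2 and fell in 2 of 14, with Tgfbi at 1.16 and Fn1 at −0.21, the latter at 18.68 to 19.19 in the male arrays, above the same percentile. The oxidant production and antioxidant genes (adjusted p = 0.0835) rose in 6 and fell in 3 of 14, with the phagocyte oxidase gene Cybb at 2.32 and the smooth muscle oxidase gene Nox4 at −1.93. Steroid hormone receptor and response genes (adjusted p = 0.104) fell in 3 of 8, with the oestrogen receptor gene Esr1 at −0.71 and the mineralocorticoid receptor gene Nr3c2 at −0.69.

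The remaining lists were not called in males. These were the markers of B and plasma cells (adjusted p = 0.71, 0 of 11 members called), mast cells (0.402), lymphatic endothelium (0.122), adipocytes (0.743), nerve and ganglion (0.427), skeletal muscle (0.71), mesothelium (0.908, with a median of 0.06 and a mean of −0.01) and red blood cells (0.417). Neither were the oxidative phosphorylation (0.427), fatty acid oxidation and TCA cycle (0.122), osteochondrogenic (0.922), unfolded protein response (0.144), immediate early (0.306), Y-linked (0.446) and X-inactivation and escape genes (0.648). Male sham 4 stood apart with an adipocyte list mean of 13.23 against 8.32 to 9.35 in the other male sham arrays. It had an elastic fibre mean of 12.11 against 12.95 to 13.16. Without it, elastic fibre genes (adjusted p = 0.000397), collagens (0.0119), protease inhibitors (0.0486), lymphatic markers (0.0491) and TGF-beta and BMP genes (0.00345) were called lower. In the same fit oxidative phosphorylation genes (3.68e-05) and, with the opposite sign to that over all arrays, adipocyte markers (0.0247) were called higher. Matrix proteases were called without male sham 2 (0.0202) or male sham 3 (0.00835). Oxidant genes were called without male sham 2 (0.0335), male sham 3 (0.0425) or male PPE 1 (0.0388), and unfolded protein response genes without male sham 3 (0.0383). The same held for lymphatic markers (0.0389) and fatty acid oxidation genes (0.00818) without male sham 5, and elastic fibre genes without male PPE 3 (0.0477). TGF-beta and BMP genes were called without male PPE 2 (0.0392), male PPE 3 (0.0245), male PPE 4 (0.0464) or female PPE 4 (0.047). None of the 16 lists called in males lost its call in a fit without 1 array.

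**Figure D1:**
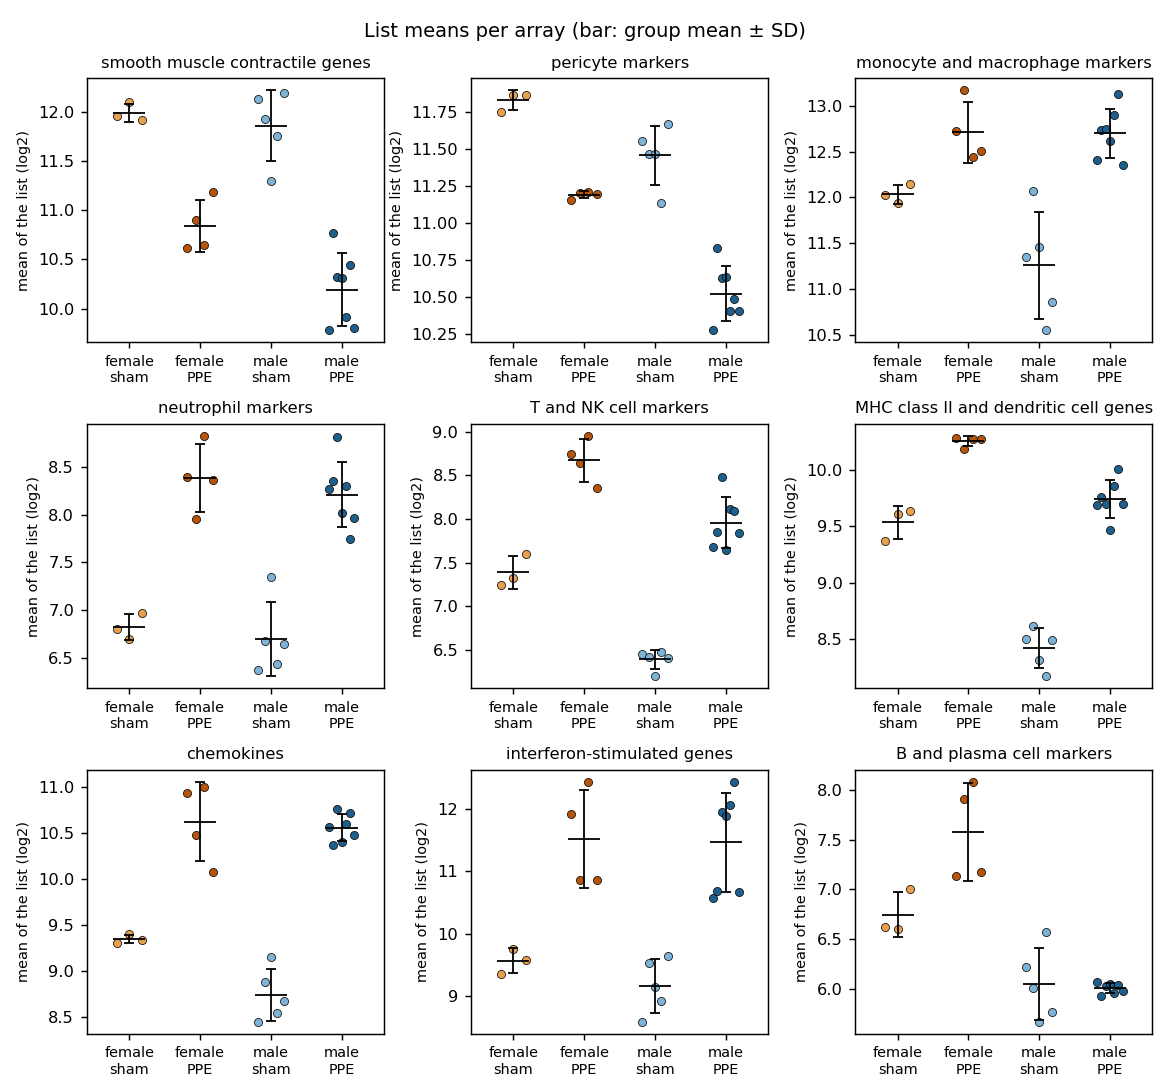
Mean log2 value of the members of 9 gene lists in each array (vertical axis), by group (horizontal axis: 3 female sham, 4 female PPE, 5 male sham and 7 male PPE arrays), each point 1 mouse, with bars for the group mean ± SD. Smooth muscle contractile genes averaged 11.86 in male sham and 10.19 in male PPE and 11.99 and 10.84 in the female groups, while T and NK cell markers went from 6.40 to 7.96 in males and from 7.39 to 8.67 in females.

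In females, PPE was followed by a rise of neutrophil, T and NK cell, MHC class II and chemokine genes and a fall of pericyte genes. Interferon-stimulated genes rose and smooth muscle genes fell with the preset correlation, with adjusted p = 0.0776 and adjusted p = 0.0545 with an estimated correlation. Slfn4 rose from 8.01 in sham to 13.04 in PPE (5.03 ± 0.79, SE, 32.8-fold, adjusted p = 0.00262, n = 3 and 4), and Cxcl9 rose by 3.75 ± 0.59 (13.5-fold, adjusted p = 0.00274). The calprotectin gene S100a8 (3: 90669071 to 90670034) rose by 3.68 ± 0.60 (12.8-fold, adjusted p = 0.00301) and its partner S100a9 by 3.31 ± 0.51 (adjusted p = 0.00252). Among the genes named by rule Sytl5, a gene of vesicle traffic (X: 9747622 to 9998864), showed the largest fall, from 11.36 to 8.45 (−2.92 ± 0.52, 7.55-fold, adjusted p = 0.00499), followed by Cytl1 (−2.63 ± 0.44, adjusted p = 0.00355).

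The further rising genes named by rule in females were Ms4a4c (3.51), Slfn1 (3.42), Saa3 (3.41, with female PPE 2 at 10.97 against 12.43 to 12.54 in the other PPE arrays), and Irf7, a regulator of type I interferon genes (2.82). They also included the neutrophil granule gene Ngp (2.81), Il1b (2.81), Ms4a4b (2.74) and Ifi213 (2.71). The further falling genes were the clock genes Npas2 (−2.55) and Arntl, which encodes BMAL1 (−1.77), Ccdc3 (−2.53) and Pdlim3 (−2.35). Itga8 (−2.19) had female PPE 4 at 14.64 against 13.38 to 13.45 in the others. To these came the deiodinase gene Dio2 (−1.99), Lmcd1 (−1.98), calponin (Cnn1, −1.96), Osr1 (−1.82) and Ntrk3 (−1.80). The rule admitted only genes for which all 4 PPE arrays lay on the same side of all 3 sham arrays. A further 3 rising and 1 falling transcripts of that size had skipped names. Of the 24, 8 rising and 5 falling genes kept their call in all 19 fits that left out 1 array. Calls were lost without female sham 2 for Irf7, Il1b, Npas2, Itga8, Cnn1 and Arntl and without female sham 1 or 2 for Ifi213 and Pdlim3. They were lost without these or female PPE 3 for Ngp, without these or female PPE 1 or 3 for Ccdc3, and without any female array but PPE 2 and 4 for Osr1. Myh11 at −1.65 ± 0.47 did not pass (adjusted p = 0.0553), nor did Hspb7 (−1.15) and Susd5 (−1.08), for both of which female PPE 4 stood apart, or Fmo2 (−1.54).

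In total 1273 genes were called in females, 835 higher and 438 lower (65.6% higher), of which 498 changed at least 2-fold. After quantile normalization 44.1% of 1525 called genes were higher. The count fell to 568, 368 and 721 without female sham 1, 2 and 3 and to 670, 821 and 649 without female PPE 1, 2 and 3. It was 2454 without the 3 male arrays that stood apart, male sham 4 and 5 and male PPE 1, which enter through the shared variance. With a score of clock genes as a covariate 3315 genes were called in females, of which 886 were among the 1273. Within groups this score varied mostly among male sham arrays (SD 2.25, against 0.23 to 0.71 in the other groups). It also changed with PPE in females itself (3.14), so this fit cannot separate the clock from PPE in females. Other splits of the female arrays called at most 559 genes, below the real count, with only 35 splits possible. They called up to 29 lists against 24, so chance cannot be excluded for the count of lists.

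Lymphocyte, antigen presentation and chemokine lists rose in females. T and NK cell markers rose in 13 of 15 members (median 1.36, adjusted p = 2.35e-22, and 0.0133 with an estimated correlation), with Cd3e at 1.72 and Cd8a at 1.51. MHC class II and dendritic cell genes rose in 8 of 13 (median 0.77, adjusted p = 1.15e-12, and 0.0133 with an estimated correlation), with Ciita at 1.10. Chemokines rose in 6 of 19 and in 12 adjusted over the list alone (median 0.98, adjusted p = 5.25e-12, and 0.0176 with an estimated correlation). Ccl5 was at 2.26 (female PPE 4 at 10.37 against 11.22 to 11.39 in the others) and Cxcl12 at 1.37. Neutrophil markers rose in 5 of 12 and in 9 adjusted over the list alone (median 1.34, adjusted p = 8.41e-12, and 0.0282 with an estimated correlation). Interferon-stimulated genes rose in 9 of 14 (median 2.00, adjusted p = 2.72e-16, and adjusted p = 0.0776 with an estimated correlation), with Gbp2 at 1.91. Inflammatory cytokine and inflammasome genes rose in 7 of 18 (median 0.89, adjusted p = 2.02e-10, and adjusted p = 0.0545 with an estimated correlation), with Il1rn at 2.17. Monocyte and macrophage markers rose in 3 of 18 (median 0.66, adjusted p = 5.27e-07, and adjusted p = 0.27 with an estimated correlation). Fcgr1 was at 1.86 and Aif1 at 0.73, and Cd68 at 0.86 and Adgre1 at 0.80 were not called. B and plasma cell markers rose in 2 of 11 and in 7 adjusted over the list alone (median 0.95, adjusted p = 2.27e-06, and adjusted p = 0.133 with an estimated correlation). The antigen receptor gene Cd79b was at 1.14 and Ms4a1, which encodes CD20, at 2.05. Both were highest in female PPE 2 and 3, where Ms4a1 read 9.85 and 10.42 against 8.47 and 8.5 in female PPE 1 and 4.

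The contractile lists fell in females. Smooth muscle contractile genes fell in 10 of 17 members and in 15 adjusted over the list alone (median −1.09, adjusted p = 2.64e-15, and adjusted p = 0.0545 with an estimated correlation), with Acta2 at −0.84 and Smtn at −0.82. Pericyte markers fell in 4 of 8 (median −0.71, adjusted p = 1.11e-05, and 0.0166 with an estimated correlation), with Rgs5 at −1.12 and Abcc9 at −1.05. Resident fibroblast markers fell in 2 of 9 and in 8 adjusted over the list alone (median −0.73, adjusted p = 3.11e-07, and adjusted p = 0.0776 with an estimated correlation), with Pi16 at −1.07 and Cd34 at −0.72. Elastin was at −0.73 without a call, and Ltbp4 fell by 1.26. With the preset correlation the cell cycle (median 0.33, adjusted p = 2.55e-06, 0 of 22 members called), complement and coagulation (0.43, 0.00341) and Y-linked lists (−0.16, 0.0236, in arrays without a Y chromosome) were also called. So were oxidative phosphorylation genes (−0.23, 0.00176) and fatty acid oxidation and TCA cycle genes (−0.52, 0.000775). None of these 5 kept the call with an estimated correlation, where adjusted p was 0.418, 0.27, 0.177, 0.51 and 0.51 in that order. The adipocyte list mean ran from 11.44 to 12.27 in female sham and from 9.72 to 11.73 in female PPE arrays.

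A further 8 lists were called in females with the preset correlation and lost the call both with an estimated correlation and in fits without 1 array. Elastic fibre genes (median −0.35, adjusted p = 0.00962, and adjusted p = 0.407 with an estimated correlation) and activated fibroblast genes (−0.41, 0.00702, and adjusted p = 0.407 with an estimated correlation) had 0.0505 and 0.153 without female sham 1. Collagens (−0.11, 0.0374, and adjusted p = 0.515 with an estimated correlation) had 0.831 without female sham 1, 0.0559 without female PPE 1 and 0.0533 without female PPE 3. With the clock score as a covariate the elastic fibre (adjusted p = 0.875), activated fibroblast (0.979) and collagen lists (0.34) turned direction. That score varied within groups mostly among male sham arrays and changed with PPE in females, so these turns do not show that the lists follow the clock. Skeletal muscle markers (−0.81, 0.0278, and adjusted p = 0.515 with an estimated correlation) averaged 9.87 in female sham 1 and 8.76 in female PPE 2 against 5.77 to 5.97 in the other female arrays. The list turned direction without female sham 1 (0.0836) and had 0.127, 0.14 and 0.125 without female PPE 1, 3 and 4. Adipocyte markers (−0.84, 0.00962, and adjusted p = 0.515 with an estimated correlation) had 0.101 without female sham 2 and 0.0606 without female PPE 2. Nerve and ganglion markers (0.26, 0.00206, and adjusted p = 0.407 with an estimated correlation) and lysosome genes (0.21, 0.000812, and adjusted p = 0.407 with an estimated correlation) had 0.142 and 0.0542 without female PPE 2. Immediate early genes (0.27, 0.0485, and adjusted p = 0.515 with an estimated correlation) turned direction without female sham 3 (0.902). They had 0.074, 0.142 and 0.0618 without female PPE 2, 3 and 4 and 0.0552, 0.0529, 0.0505 and 0.0501 without male sham 3 and male PPE 1, 2 and 4.

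The lists not called in females were matrix proteases (adjusted p = 0.165), protease inhibitors (0.051), mast cell markers (0.0681), endothelial (0.175, with a median of −0.00 and a mean of −0.15), lymphatic endothelial (0.105), mesothelial (0.109) and red blood cell genes (0.327). The same held for glycolysis and hypoxia (0.296), osteochondrogenic (0.461), TGF-beta and BMP (0.175), oxidant (0.18), unfolded protein response (0.139), circadian clock (0.724), steroid hormone (0.175) and X-inactivation genes (0.627). Without female sham 1, matrix proteases (0.0384), mast cell markers (0.0225) and oxidant genes (0.0418) were called. Without female sham 3, mast cell (0.0154), endothelial (0.00703), lymphatic (0.0189), TGF-beta and BMP (0.0154) and steroid hormone genes (0.0232) were. Protease inhibitors were called without female sham 2 (0.0489), female PPE 3 (0.027), female PPE 4 (0.0225), male sham 1 (0.0488), male sham 4 (0.019) or male PPE 4 (0.0493). Mast cell markers were called without female PPE 2 (0.0479), female PPE 4 (0.0163) or male PPE 5 (0.0429), steroid hormone genes without female PPE 4 (0.021) and lymphatic markers without male sham 2 (0.039).

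**Figure D2:**
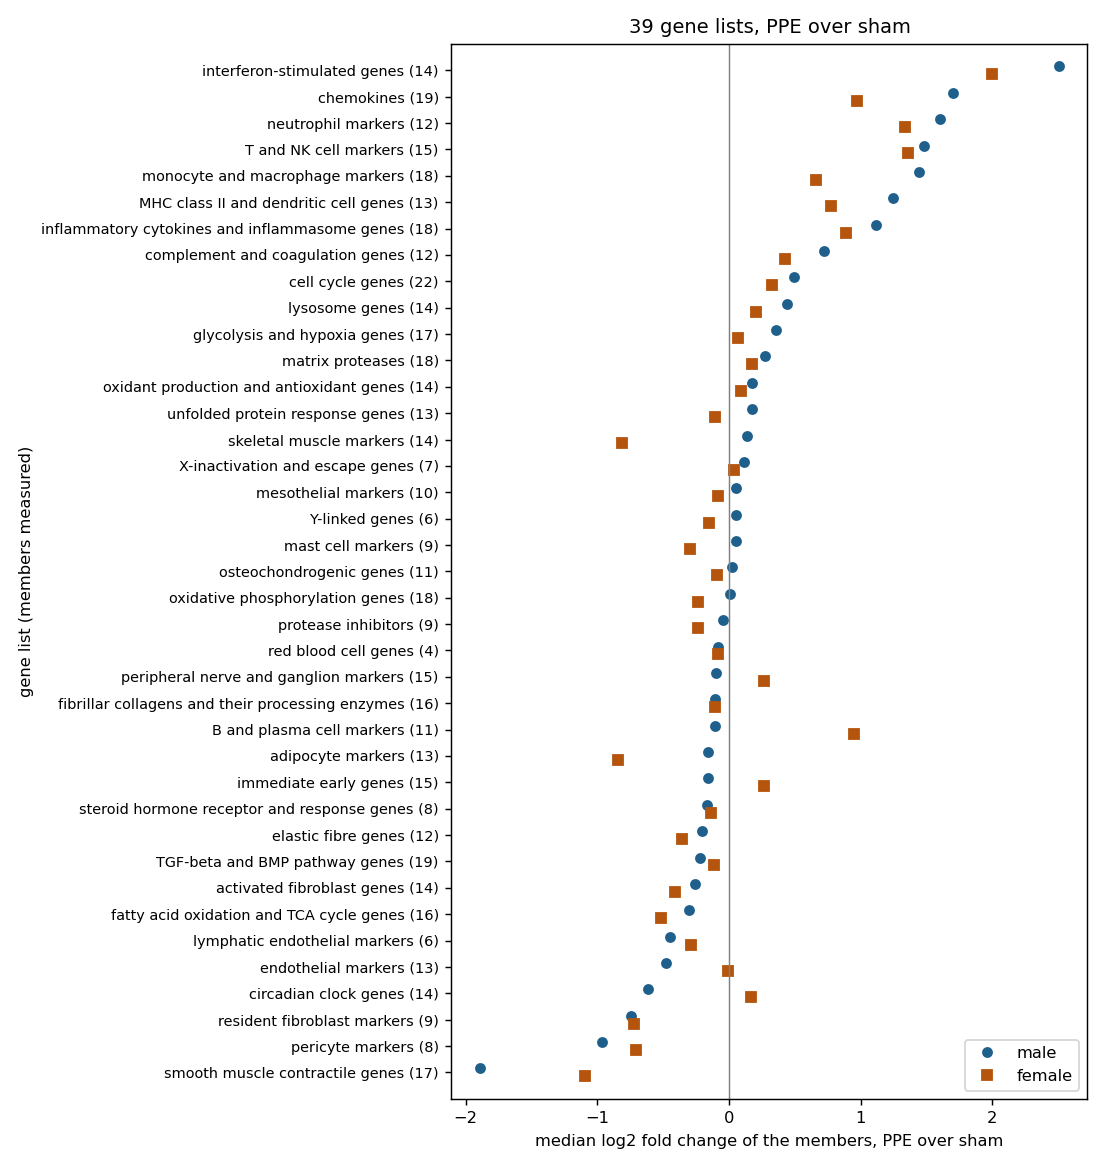
Median log2 fold change of the members (horizontal axis, PPE over sham) of the 39 gene lists (vertical axis, measured members in parentheses), with circles for males (7 PPE, 5 sham) and squares for females (4 PPE, 3 sham). Interferon-stimulated genes stood highest in both sexes (2.50 and 2.00) and smooth muscle contractile genes lowest (−1.89 and −1.09).

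The responses of the sexes shared many genes. Of the genes called higher, 740 were called in both sexes against 80.8 if the calls were independent, and of those called lower 394 were shared against 43.7, while 21 genes were called in opposite directions. Both sets of calls used the same residual variance per gene. They are therefore not independent even without a shared response, and 80.8 and 43.7 are no exact chance levels. Of the 835 genes higher in females 96.5% had the same sign in males, and of the 438 lower in females 97.7% did. Of the genes called in males, 91.2% of those higher and 75.4% of those lower had the same sign in females. Across all genes the male and female log2 fold changes correlated with r = 0.494 (Spearman rho 0.321), and across the 1273 genes called in females with r = 0.891 (rho 0.879), and across the 5923 called in males with r = 0.667 (rho 0.661), where genes are not independent replicates. Averaged over the sexes 5056 genes were called, 2770 higher and 2286 lower.

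**Figure D3:**
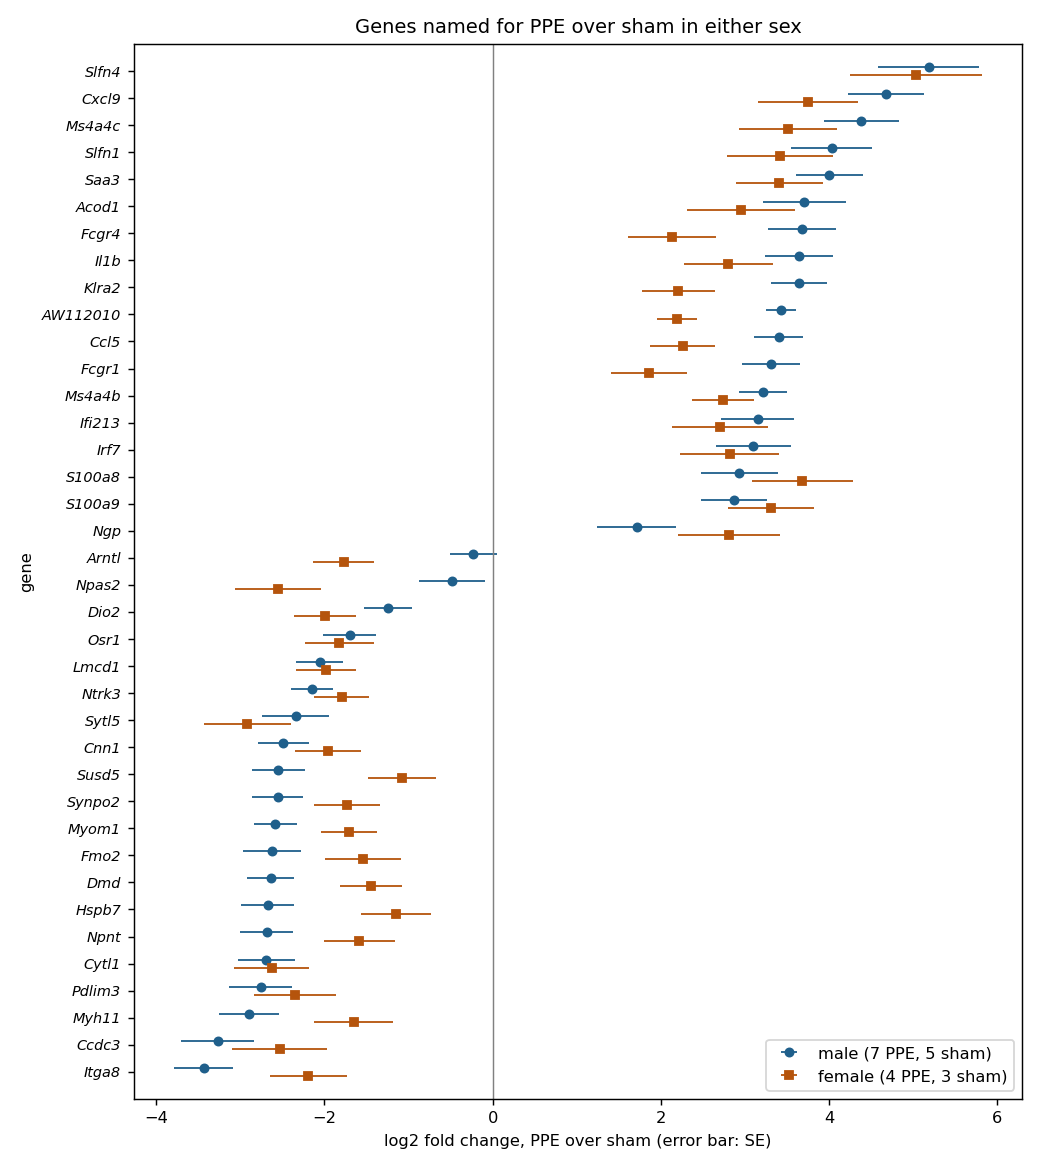
Log2 fold change of PPE over sham (horizontal axis) for the genes named by rule in either sex (vertical axis), with circles for males (7 PPE, 5 sham) and squares for females (4 PPE, 3 sham) and error bars for the SE of the limma fit. Slfn4 stood at 5.19 and 5.03, Itga8 at −3.44 and −2.19, and Npas2 at −0.48 in males and −2.55 in females.

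The difference between the sexes in the response to PPE was called for few protein-coding genes. With sensory receptor and small RNA genes left out of the tests only 3 genes were called, so most of the genes named here then lost their call. Klrb1b, a receptor gene of natural killer cells (6: 128813706 to 128826315), rose by 2.96 in males and by 1.15 in females, a difference of 1.81 ± 0.26 (SE, adjusted p = 0.0134). The larger male rise was also called for the MHC class II gene H2-Eb1 (2.75 against 1.14, adjusted p = 0.0429), Plbd1 (2.63 against 1.26, adjusted p = 0.0242) and Ly6i (1.95 against 0.51, adjusted p = 0.0429). It was called at under 1 log2 unit for the glycolytic gene Tpi1 (0.72), Eef1e1 (0.67), the chemokine receptor gene Cxcr3 (0.64), Slc25a5 (0.60) and Cdca4 (0.56). The difference for Mesp1 (0.34) came mostly from females, at −0.23 against 0.11 in males. H2-Eb1 stood apart in male sham 4 (10.88 against 11.71 to 12.04), Cdca4 in male PPE 7 (8.03) and Eef1e1 in female PPE 2 (10.6). All 7 male PPE arrays exceeded all 5 male sham arrays for each of these genes except Mesp1, and all 4 female PPE arrays exceeded all 3 female sham arrays for Klrb1b, H2-Eb1, Plbd1 and Slc25a5.

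Most calls of this comparison concerned repeated gene families. Of 163 called genes 12 had a more positive and 151 a more negative PPE change in males than in females. Of the 163, 90 lay in a block of small RNA genes on chromosome 7 and 13 were sensory receptor genes (0.75% of 1733, against 0.54% of all genes). The 163 genes had only 109 distinct sets of values, so the count is not one of separate measurements. The block had a median change of −1.50 in males and 1.44 in females over its 167 genes. Its mean went from 7.81 ± 0.61 (SD) in male sham to 6.42 ± 0.77 in male PPE and from 6.92 ± 0.23 in female sham to 8.28 ± 0.30 in female PPE. Among the vomeronasal receptor genes, which the nose uses to sense pheromones, Vmn1r114 (7: 20811221 to 20812186) was at −2.08 in males and 0.73 in females (difference −2.81 ± 0.57, adjusted p = 0.0295). The genes Vmn1r121 (−2.64), Vmn1r149 (−2.11), Vmn1r101 (−2.01), Vmn1r-ps79 (−1.88), Vmn1r-ps74 (−1.63), Vmn2r36 (−1.10) and Vmn2r38 (−1.01), the odorant receptor gene Olfr68 (−1.14) and the protease gene Mep1b (−1.19) differed the same way. Within the 12 male arrays the called receptor genes followed the Y-linked repeated genes Sly and Orly (deviations from the group means, r = 0.960, permutation p = 1e-05, the smallest the permutations can give). The rank correlation was of the same size (Spearman rho 0.935, permutation p = 4e-05, r = 0.959 without the 2 arrays farthest from the median, adjusted p = 2e-05 over 4 relations). For the value without 2 arrays the group means still included them. Olfr68 stood apart in male PPE 2 (4.92) and Vmn2r38 in male PPE 6 (6.53).

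The count of 163 rested on few arrays. It was 0 without female sham 1 or female sham 2, 88, 7 and 12 without female PPE 1, 3 and 4, 29, 426 and 35 without male sham 1, 3 and 5. It was 79 without the 3 male arrays that stood apart (36 of them shared), 3 without sensory receptor and small RNA genes in the tests, and 3 with a score of clock genes as a covariate (0 shared). The clock score itself differed between the responses by −4.02 and varied within groups mostly among male sham arrays. The fit with this covariate thus cannot tell whether the 163 differences depend on the clock. The count rose to 422 with the 3 arrays as a batch term and to 674 with the adipocyte score as a covariate, with all 163 shared in both. None of the named genes of this comparison kept its call in all 19 fits without 1 array. Klrb1b kept it in 17, Vmn1r-ps79 in 15, Mep1b in 14 and Plbd1 in 13, while H2-Eb1 and Tpi1 kept it in 5, Ly6i and Eef1e1 in 4 and Slc25a5 and Mesp1 in 3. After quantile normalization 223 genes were called, 68 with a more positive and 155 with a more negative change in males (30.5% more positive against 7.36%). Other splits called at most 5 genes, below the real count, and up to 23 lists against 19, so chance cannot be excluded for the lists.

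With the preset correlation 19 of the 39 lists differed between the responses, and with an estimated correlation 0 did. The MHC class II and dendritic cell genes had a larger rise in males (median difference 0.48, 1 of 13 members called and 8 adjusted over the list alone, adjusted p = 3.57e-06, and adjusted p = 0.16 with an estimated correlation). Monocyte and macrophage markers differed by a median of 0.80 (0 of 18 called, adjusted p = 3.57e-06, and adjusted p = 0.407 with an estimated correlation) and glycolysis and hypoxia genes by 0.39 (0 of 17 called, 4 adjusted over the list alone, adjusted p = 0.000107, and adjusted p = 0.16 with an estimated correlation). B and plasma cell markers differed the other way (−0.79, 0 of 11 called, 5 adjusted over the list alone, adjusted p = 5.86e-06, and adjusted p = 0.212 with an estimated correlation), as did smooth muscle contractile genes (−0.53, 0 of 17 called, adjusted p = 0.000497, and adjusted p = 0.489 with an estimated correlation). Circadian clock genes also differed (−0.78, 0 of 14 called, 11 adjusted over the list alone in opposite directions, 2 up and 9 down, adjusted p = 0.000211, and adjusted p = 0.16 with an estimated correlation). For these 6 lists no fit without 1 array lost the call, and with the clock score as a covariate the macrophage list turned direction (0.282). The MHC class II list averaged 8.42 in male sham and 9.74 in male PPE, and 9.53 and 10.25 in the female groups. The macrophage list averaged 11.26 and 12.70 in males and 12.03 and 12.71 in females. The larger male changes thus started from lower sham values. Most genes read lower in males, so these levels do not rank the sexes after PPE.

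The other 13 lists called with the preset correlation had 0 members called over all genes. Higher in the male response were oxidative phosphorylation genes (0.35, adjusted p = 0.000329, and adjusted p = 0.575 with an estimated correlation), mast cell markers (0.79, 0.00451, estimated 0.407), chemokines (0.52, 0.00451, estimated 0.407), inflammatory cytokines (0.23, 0.00451, estimated 0.489), unfolded protein response genes (0.37, 0.00451, estimated 0.212) and Y-linked genes (0.22, 0.00451, estimated 0.16). Also higher were lysosome genes (0.25, 0.00771, estimated 0.598), skeletal muscle markers (0.93, 0.0196, estimated 0.719), T and NK cell markers (0.22, 0.0232, estimated 0.605) and cell cycle genes (0.19, 0.0283, estimated 0.785). With the clock score as a covariate the lysosome (adjusted p = 0.0267), cell cycle (adjusted p = 0.00235) and unfolded protein response lists (adjusted p = 0.955) turned direction, and without the 3 male arrays that stood apart the cell cycle list did (adjusted p = 0.565). Lower were nerve and ganglion markers (−0.67, 0.000419, estimated 0.407), immediate early genes (−0.26, 0.00323, estimated 0.489) and endothelial markers (−0.20, 0.00711, estimated 0.407). Without female sham 1 the call was lost for skeletal muscle (0.354, opposite direction), cell cycle (0.231) and lysosome genes (0.0699), without female sham 2 for mast cells (0.0694), and without female sham 3 for T and NK cells (0.143), endothelium (0.203), immediate early (0.213) and cell cycle genes (0.127). Without female PPE 4 it was lost for chemokines (0.0609), cytokines (0.0636), cell cycle (0.0636), skeletal muscle (0.0759) and T and NK cells (0.146). Without female PPE 3 it was lost for skeletal muscle (0.105), lysosome (0.0811) and cell cycle genes (0.227), and without female PPE 1 for skeletal muscle (0.0887). Among the male arrays, leaving out sham 4 lost lysosome (0.0728) and cell cycle genes (0.76), sham 5 the same lists (0.0658 and 0.108), sham 3 T and NK cells (0.0762) and PPE 3 T and NK cells (0.124) and cell cycle genes (0.0738). Cell cycle genes also lost it without male PPE 2 (0.0808) or 7 (0.0513), and skeletal muscle without male PPE 6 (0.0597).

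The remaining 20 lists were not called in this comparison. Leaving out male sham 4 brought calls for adipocyte markers (8e-09), fatty acid oxidation genes (6.17e-14), mesothelial (0.00234) and pericyte markers (0.0196) and TGF-beta and BMP genes (0.0415). Activated fibroblast genes were called without female sham 2 (0.0233) or 3 (0.00689), female PPE 2 (0.0135), male sham 2 (0.0233) or 3 (0.0093) or male PPE 5 (0.0473), and adipocyte markers without female sham 3 (0.00689), female PPE 4 (0.00582) or male PPE 1 (0.0469). Interferon-stimulated genes were called without female PPE 3 (0.0138) or male PPE 1 (0.0403), complement genes without male sham 2 (0.0233), matrix proteases without male sham 3 (0.0425), oxidant genes without female sham 3 (0.0488), fatty acid oxidation genes without female PPE 4 (0.0428) and pericyte markers without male PPE 2 (0.031).

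Clock genes varied widely among male sham arrays. A clock score, the mean of Dbp, Nr1d1 and Per3 minus the mean of Arntl and Npas2, chosen after the values were seen, changed by 3.14 ± 0.93 (SE) in females, from −1.45 ± 0.71 (SD, n = 3) to 1.69 ± 0.23 (n = 4), with no test given because Arntl and Npas2 entered it after their fall was seen. It changed by −0.88 ± 0.72 in males, from −0.58 ± 2.25 (n = 5) to −1.46 ± 0.39 (n = 7). The changes differed by −4.02 (95% interval −6.53 to −1.52). Male sham 4 and 5, at 1.66 and 2.02, held the highest scores among the male arrays, and without them the male change was 0.73, in the same direction as in females. The opposite sign of the score in males thus rests on these 2 arrays, but Dbp did not rise in males even without them. Dbp read 8.46, 7.5 and 7.72 in male sham 1, 2 and 3 and 7.33 to 7.91 in male PPE. It read 8.31 to 9.42 in female sham and 10.27 to 11.01 in female PPE. Arntl (10.36 to 10.71 in male sham 1 to 3, 9.24 to 9.82 in male PPE) and Npas2 (10.07 to 10.33 and 8.47 to 8.93) fell in males as in females.

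**Figure D4:**
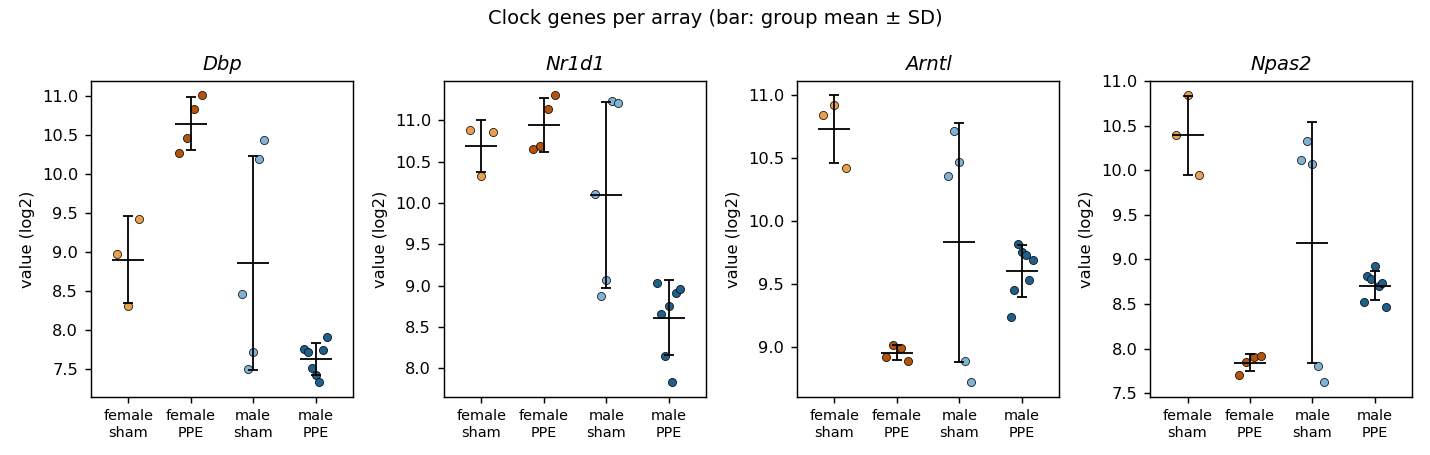
Log2 values of 4 clock genes in each array (vertical axis), by group (horizontal axis), each point 1 mouse, with bars for the group mean ± SD. Female PPE arrays were high in Dbp (mean 10.64) and low in Arntl (8.96) and Npas2 (7.84), while male sham arrays fell into 2 sets that differed in all 4 genes.

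Most genes read lower in males than in females in both conditions. Among sham aortae 21653 genes were called, 662 higher and 20991 lower in males (3.06% higher), and among PPE aortae 23403, 457 higher and 22946 lower (1.95% higher), with medians over all genes of −0.48 and −0.48. The split depended on the scaling. Quantile normalization gave 9088 called genes among sham aortae (36.6% higher in males) and 9642 among PPE aortae (51.0%), and centring each array on its median gave 8189 (50.5%) and 10048 (63.6%). Sex and any separate handling of the male and female arrays cannot be told apart here, so the differences below are given relative to the median of all genes. Other splits called up to 11830 genes among sham and 13093 among PPE aortae, below both real counts. Of the lists 13 and 24 were called on the deposited values, and 1 in each condition, the Y-linked genes, with an estimated correlation.

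Sex chromosome genes led the differences between male and female sham aortae. The lists of mast cell (adjusted p = 0.2), adipocyte (adjusted p = 0.462) and skeletal muscle markers (adjusted p = 0.967) were not called, although single members were among the genes named. The Y-linked Uty (5.84), Eif2s3y (5.47), Kdm5d (4.43), Orly (4.49) and Sly (3.09) stood above the shift, and were followed by S100a8 (2.43), the collagen VI gene Col6a5 (2.34), the complement gene C7 (2.29), Astx6 (2.03) and Astx1a (1.96). Below it were Xist (−10.47), the urinary protein genes Mup-ps5 (−5.26) and Mup20 (−2.88), the muscle light chain gene Myl1 (−3.64), the mast cell protease genes Cpa3 (−3.53) and Mcpt4 (−2.88) and Retnla (−3.34). The lipogenic genes Thrsp (−3.07) and Fasn (−2.88) and Tmem45b (−3.06) were lower too. The value of Myl1 was carried by female sham 1, at 14.73 against 8.6 and 7.52 in the other female sham arrays. Fasn was lower in males although male sham 4 stood at 14.54 against 9.56 to 10.73 in the other male sham arrays. Of the lists, Y-linked genes were higher (3 of 6 higher and 2 lower, adjusted p = 1.56e-11, and 0.000648 with an estimated correlation) and X-inactivation and escape genes lower (7 of 7, adjusted p = 0.00233, and adjusted p = 0.579 with an estimated correlation). Immediate early genes were higher relative to other genes (1 of 15 higher and 2 lower, adjusted p = 4.45e-05, and adjusted p = 0.579 with an estimated correlation) too, and these 3 lists were called under all 3 scalings.

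Among PPE aortae, the B cell gene Ms4a1 stood at −2.57 relative to the median of all genes, from 9.31 in female to 6.26 in male PPE aortae, and Fcmr, the receptor gene for immunoglobulin M, at −2.46. All 11 B and plasma cell markers were called lower on the deposited values, where 22946 of 30142 genes were, and relative to other genes the list was lower (median −1.10 relative to all genes, adjusted p = 0.0312, and adjusted p = 0.553 with an estimated correlation), a call lost without male PPE 1 (0.0653). Also lower were Xist (−10.58), Mup-ps5 (−4.81), Mup20 (−2.55), the X-linked repeated genes Btbd35f18 (−2.74), Btbd35f5 (−2.54) and Btbd35f16 (−2.53), of which Btbd35f18 and Btbd35f16 stood apart in female PPE 2 (7.99 and 7.69). Also lower were Dbp (−2.54) and Cd209b (−2.66), which read 8.74 and 9.24 in female PPE 2 and 3 and 5.91 and 7.3 in female PPE 1 and 4. Higher were Uty (6.06), Eif2s3y (5.90), Kdm5d (4.51), C7 (2.76), Orly (2.48), Sly (1.83), Il1b (1.72), S100a8 (1.67), A2m (1.67) and the metallothionein gene Mt2 (1.65). Y-linked genes (4 of 6 higher and 1 lower, adjusted p = 2.01e-19, and 3.08e-05 with an estimated correlation) were higher and X-inactivation genes (7 of 7, adjusted p = 0.00143, and adjusted p = 0.195 with an estimated correlation) lower under all 3 scalings. Collagens (adjusted p = 7.83e-09, and adjusted p = 0.199 with an estimated correlation) and glycolysis and hypoxia genes (adjusted p = 1.23e-05, and adjusted p = 0.085 with an estimated correlation) were higher relative to other genes under the same scalings.

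Correlations of each array with the others of its group averaged between 0.984 and 0.995, and the first 3 principal components held 49.7%, 18.4% and 7.80% of the variance. Male sham 4 and 5 and male PPE 1 had higher lowest-percentile values than the other male arrays and high positions on the third component (33.6, 27.8 and 49.5, the other male arrays lying between −29.5 and 13.2). Their array weights in limma were 0.257, 0.311 and 0.274, against 0.583 to 1.916 in the other male arrays. Mast cell markers averaged 8.57 and 8.11 in female sham and PPE aortae and 6.90 and 7.14 in the male groups, with male PPE 5 at 7.89, where Cpa3 (10.82) and Mcpt4 (9.57) stood apart.

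**Figure D5:**
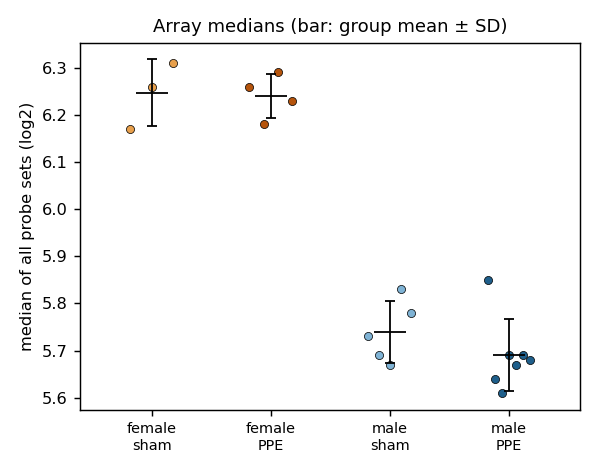
Median log2 value of all probe sets in each array (vertical axis), by group (horizontal axis), each point 1 mouse, with bars for the group mean ± SD. The 7 female arrays lay between 6.17 and 6.31 and the 12 male arrays between 5.61 and 5.85.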

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

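Of the tests in this part, those of time of day and of a shared response for the clock genes, that of genomic DNA with sensory receptor genes and the splits of arrays into other groups were chosen only after the result was seen. Arrays far from the others of their group were sought in groups of 4 or more with a gap test that chance passes in about 1 of 20 groups. Among 117 tests of lists 11 passed against 5.85 expected by chance, and among 246 tests of genes 22 against 12.3, with several on the same array.

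Male sham 4 stood apart in the adipocyte markers (13.23, others 8.32 to 9.35), fatty acid oxidation and TCA cycle genes (11.64, others 9.27 to 9.63), oxidative phosphorylation genes (9.73, others 8.63 to 8.66) and elastic fibre genes (12.11, others 12.95 to 13.16). Its genes that stood apart were Fasn (14.54, others 9.56 to 10.73), Cd209b (10.11, others 4.5 to 4.78), H2-Eb1 (10.88, others 11.71 to 12.04), Ccl5 (7.03, others 7.55 to 7.76) and Myl1 (7.39, others 5.68 to 6.07). Male sham 3 stood apart in the T and NK cell markers (6.2, others 6.41 to 6.47) and Ngp (6.05, others 4.76 to 5.02). Male PPE 5 stood apart in the mast cell markers (7.89, others 6.8 to 7.19), Cpa3 (10.82, others 7.36 to 8.69) and Mcpt4 (9.57, others 7.3 to 8.23). Male PPE 6 did so in the skeletal muscle markers (6.84, others 5.17 to 5.56), Myl1 (9.39, others 6.12 to 6.27) and Vmn2r38 (6.53, others 6.06 to 6.19), male PPE 7 in Cdca4 (8.03, others 8.2 to 8.3) and male PPE 2 in Olfr68 (4.92, others 4.43 to 4.59).

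Female PPE 2 stood apart in the skeletal muscle markers (8.76, others 5.77 to 5.85), MHC class II and dendritic cell genes (10.19, others 10.27 to 10.28) and osteochondrogenic genes (6.36, others 6.67 to 6.68). Its genes were Myl1 (13.48, others 6.95 to 7.6), Saa3 (10.97, others 12.43 to 12.54), Eef1e1 (10.6, others 10.48 to 10.5), Btbd35f18 (7.99, others 8.93 to 9.06) and Btbd35f16 (7.69, others 8.62 to 8.78). Female PPE 3 stood apart in the endothelial markers (10.45, others 10.65 to 10.67). Female PPE 4 did so in Itga8 (14.64, others 13.38 to 13.45), Hspb7 (11.2, others 9.72 to 9.96), Susd5 (9.68, others 8.88 to 9), Ccl5 (10.37, others 11.22 to 11.39) and Retnla (10.33, others 7.14 to 7.48).

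The response to PPE differed between the sexes for 163 genes and, with the preset correlation, 19 lists. With an estimated correlation 0 lists were called (camera, against 5 with fry), and 14 of 100 splits of the arrays gave as many as 19. Among 35352 probe sets without 1 gene symbol 4637 were called in males (13.1%, against 18.1% of the others) and 497 in females (1.41%, against 3.19%).

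Most genes read lower in males than in females. Between the sham groups the medians of 10 brightness classes ranged over 0.159 log2 units, which fits a constant offset between the arrays of the sexes. Between the PPE groups they ran from −0.568 to −0.362, the latter in the brightest class. That is a wider range, which the test did not cover. After quantile normalization 23.37% of 1733 sensory receptor genes, which an aorta should not use, were still called between the sham groups, against 30.6% of other genes, which fits handling of the arrays of each sex as a batch. Sex and batch are confounded here, and an effect of sex itself was not tested apart from it.

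The PPE change of clock genes differed between the sexes. Over the 19 arrays Arntl and Npas2 deviated from their group means against Dbp, Nr1d1 and Per3 (r = −0.926, permutation p = 1e-05, the smallest the permutations can give, Spearman rho −0.847, permutation p = 2e-05, r = −0.859 without the 2 farthest arrays), which fits differences in the time of day at harvest. Anything else that shifts the clock would move these genes the same way, so the relation cannot tell time of day from other causes. The value without the 2 farthest arrays used group means that still included them. It therefore does not show that the relation holds without these arrays, and the same limit applies to such values below. The changes differed by −4.023 (95% interval −6.53 to −1.517), but the score was chosen after these genes were seen to differ and the male change was 0.73 without male sham 4 and 5, so a response to PPE shared by the sexes remains open for the score. No shared rise was seen for Dbp, which was higher in female PPE than in female sham arrays. In males it read 8.46, 7.5 and 7.72 in sham 1, 2 and 3 and 7.33 to 7.91 in PPE arrays. Fat in the sample cannot be decided from r = 0.518 with the adipocyte score (permutation p = 0.0372, adjusted p = 0.0496 over 4 relations, Spearman rho 0.349, permutation p = 0.145, r = 0.539 without the 2 farthest arrays). The harvest times are not given in the sources used here, so an effect of PPE on the clock in females remains open.

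The small RNA block on chromosome 7 fell in males and rose in females, with medians of −1.50 and 1.44. The 13 called sensory receptor genes had medians of −0.93 and 0.31. They were picked because this difference was called, so their medians are no separate evidence of it. All 1733 sensory receptor genes had medians of −0.11 in males and 0.018 in females. Leaving out male sham 4 and 5 and male PPE 1 kept 87.66% of the median difference over all 163 called genes, and the 90 called genes of the block went from −3.33 to −2.92 and the 13 receptor genes from −1.14 to −1.02, so these arrays alone do not account for it. The called sensory receptor genes followed the Y-linked families Sly and Orly over the 12 male arrays (r = 0.96, permutation p = 1e-05, Spearman rho 0.935), which fits genomic DNA in the RNA, since DNA brings both. That relation was taken over the 13 called genes only and does not cover the receptor genes as a whole. For the small RNA block on chromosome 7 the same test could not tell (r = 0.53, permutation p = 0.0749, Spearman rho 0.606, permutation p = 0.0407, r = 0.299 without the 2 farthest arrays). Other causes that move both families were not tested.

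Splits of the arrays into other groups of the same sizes, with the real split counted, gave a result as large as the real count of genes in 1 of 100 splits for males (5923, highest other 1866), 1 of 35 for females (1273 and 559), 1 of 100 for the sex difference (163 and 5), 1 of 56 between sham groups (21653 and 11830), 1 of 100 between PPE groups (23403 and 13093) and 1 of 100 for the average (5056 and 3). In each case only the real split reached its count, which is the lowest share that this number of splits can give. For lists with the preset correlation the splits were 34 of 100 in males (16, highest other 27), 3 of 35 in females (24 and 29), 14 of 100 for the sex difference (19 and 23) and 43 of 56 between sham groups (13 and 29), where chance cannot be excluded, and 3 of 100 between PPE groups (24 and 25). Some of these splits keep or reverse most of the real labels and can call many genes from the real difference itself. High counts among them therefore do not show another structure among the arrays, which was not tested.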

How the results depend on the processing

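The settings with 3 male arrays left out or as a batch term, with the clock or adipocyte score as a covariate, and without sensory receptor and small RNA genes were chosen only after the result was seen. Group sizes of 3 to 7 limit every result, and low signal limits dim genes, with 1st percentiles of 3.42 and above in male and 3.77 to 3.87 in female arrays. Where no cause is given below, the cause was not tested.

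Leaving out each array in turn gave 4958 to 6365 called genes in males, 368 to 1613 in females, 0 to 426 for the sex difference, 19466 to 22135 between sham groups, 22170 to 23789 between PPE groups and 4185 to 5519 for the average. In females the count was 568, 368 and 721 without sham 1, 2 and 3 and 670, 821 and 649 without PPE 1, 2 and 3. For the sex difference it was 0 and 0 without female sham 1 and 2 (limma, where 2998 genes had an unadjusted p below 0.05 over all arrays, and camera called 16 lists without female sham 1), 88, 7 and 12 without female PPE 1, 3 and 4 and 29, 426 and 35 without male sham 1, 3 and 5. Lists called ranged over 16 to 23, 21 to 28, 16 to 22, 10 to 19 and 19 to 26 in males, females, the sex difference, sham and PPE groups.

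A 2-fold screen left 1217 genes in males, 498 in females, 2996 between sham groups, 2664 between PPE groups and 765 for the average, by its construction. Quantile normalization gave 9088 between sham and 9642 between PPE groups, and median centring 8189 and 10048 and 274 for the sex difference. Without dim genes 255 genes differed in response, 11271 between sham and 12628 between PPE groups. With every probe set tested the counts were 10186 in males, 1473 in females, 554 for the sex difference, 42471 between sham groups, 47566 between PPE groups and 7990 for the average, over 65956 probe sets. Array weights gave 3951 in females and 931 for the sex difference, and only the 2 groups compared gave 1970 in females. Male groups drawn down to the female sizes had a median of 3852 called genes (2461 to 6546), and all 100 draws lay above the 1273 of females. Both counts used the variance shared by all groups. The median SD of a gene was 0.118 and 0.121 in female sham and PPE arrays and 0.194 and 0.178 in male sham and PPE arrays. The shared variance thus overstates the female and understates the male spread, so the draws do not compare the sexes on equal terms.

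With a replicate block 64 genes differed in response (63 shared), and no other count of genes or lists moved by over 1.5 times. The replicate numbers showed no clear pairing of the samples: of 8 pairs 2 had a correlation over 0.1 (−0.321 to 0.24), and 1 correlated best with its own number. With so few pairs and no chance level for them, a shared day or litter cannot be excluded.

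Without the 3 male arrays 2454 genes were called in females and 79 for the sex difference, and as a batch term 1959 and 422. The clock score as a covariate gave 3315 in females and 3 for the sex difference, 0 of them shared, and the adipocyte score 674 for the sex difference. Within groups the clock score had an SD of 2.25 in male sham and of 0.23 to 0.71 in the other groups. It changed by 3.14 with PPE in females and differed by −4.02 between the responses. Results with this covariate, and the turns of direction below, thus cannot separate the clock from these contrasts. Without sensory receptor and small RNA genes 3 differed in response.

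With an estimated correlation 7 lists were called in males, 5 in females, 0 for the sex difference (camera, against 19 with the preset correlation and 5 with fry), 1 between sham and 1 between PPE groups. With fry 11 were called in females, 5 for the sex difference and 31 between sham groups. Quantile normalization gave 7 between sham and 6 between PPE groups, median centring 6 between PPE groups, the 3 male arrays left out 23 and as a batch term 20 between sham groups, and the clock score 10 between PPE groups. An intensity trend and the mean of a gene's probe sets moved no count of genes by over 1.5 times. The correlation of the fold changes of the sexes was 0.494, and 0.321 with Spearman.

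Some results turned direction. Without the 3 male arrays these were adipocyte markers in males (adjusted p = 0.0368), cell cycle genes in the sex difference (0.565) and Upk3b in males (log2 0.225). Without male sham 4 it was adipocyte markers in males (0.0247, 0.0247 to 0.92 over the fits without 1 array), without female sham 1 skeletal muscle markers in females (0.0836, 2.5e-06 to 0.14) and in the sex difference (0.354, 1.09e-05 to 0.354), and without female sham 3 immediate early genes in females (0.902, 0.000106 to 0.902). With the clock score as a covariate these were elastic fibre genes (0.875), collagens (0.34), activated fibroblast genes (0.979), circadian genes (0.000463) and Astx1a (log2 −1.095) in females. For the sex difference that setting turned collagens (0.0181), matrix proteases (0.0061), resident fibroblast (0.0222), macrophage (0.282), cell cycle (0.00235), complement (0.0269), lysosome (0.0267), unfolded protein response (0.955) and X-inactivation genes (0.00599). The adipocyte score turned adipocyte markers in females (0.594), by its construction, and fry gave the other direction for immediate early genes between sham groups (0.66) and glycolysis genes between PPE groups (0.0399). The fry test sets a list against no change and not against other genes, and most genes read lower in males, so these 2 values answer another question. In fits without 1 array 3841, 3673 and 3698 of 3914 results of named genes stayed the same in males, females and the sex difference, and 721, 701 and 693 of 741 results of lists.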

Other observations

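Families of genes that share the letters of their symbol were chosen only after the result was seen, 629 of them tested. With the preset correlation 65 were called in males and 56 in females, and with an estimated correlation 0 in either sex (camera, lowest adjusted p 0.226 and 0.284). Toll-like receptor genes rose in 12 of 12 members in males and 4 in females (medians 1.32 and 0.75), with Tlr1 at 2.38 ± 0.29 (SE, n = 7 and 5) and 1.78 ± 0.38 (n = 4 and 3), Tlr9 at 2.38 and 1.53 and Tlr13 at 2.05 and 1.43. Guanylate-binding protein genes rose in 7 of 7 in both sexes (1.97 and 1.61), with Gbp8 at 2.39 and 1.81 and Gbp4 at 2.33 and 1.59. The Ly49 receptor genes rose in 7 of 8 in both sexes (1.59 and 1.16), with Klra9 at 1.81 and 1.33, and the Schlafen genes in 8 and 6 of 9 (1.54 and 1.48), with Slfn8 at 2.42 and 2.18 and Slfn2 at 2.21 and 1.95. The lymphocyte GTPase genes named Gimap rose in 7 and 6 of 8 (0.59 and 0.85), with Gimap3 at 1.94 ± 0.21 and 2.03 ± 0.27 and Gimap6 at 0.47 and 1.15.

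Glutathione transferase genes of the mu class fell in 7 of 7 members in males and 6 in females (medians −0.62 and −0.77), with Gstm1 at −1.41 ± 0.22 and −1.44 ± 0.28 and Gstm2 at −0.66 and −1.03. Of the positional identity genes, 6 of 8 Hoxa genes fell in males and 1 in females (−0.59 and −0.26, adjusted p = 0.407 and 0.659 with an estimated correlation) and 6 of 9 Hoxc genes in males and 0 in females (−0.53 and −0.13, adjusted p = 0.229 and 0.559 with an estimated correlation). A difference between the sexes was not tested for these families. Small heat shock genes fell in 5 and 2 of 8 (−0.76 and −0.47).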
